A study of Homo sapiens with 10 samples.

How the data were processed

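The series holds 10 single-colour Agilent arrays, 1 per group: 6 of HaCaT cells and 4 of HEK293T cells, all labelled 48 h. Per the series record, cells were harvested that long after transfection, and whether the control cells received nucleic acid is not given in the sources used here. Per the labels, total RNA was extracted with the miRNeasy kit and labelled with Cy3. Per the file headers, the arrays lay on 4 slides. HaCaT control and wild type shared slide 1, and HaCaT R142C, R348X and scrambled shRNA shared slide 2. The TGM1 shRNA array lay on slide 3. All HEK293T arrays lay on slide 4 and were scanned on another day. Each raw file gives the signal of 62976 spots, of which 58717 are not controls. The intensity values were deposited as Agilent Feature Extraction 10.7.3.1 output: per the file headers they are background-subtracted processed signals on a linear scale, with flags for spots well above background. The series matrix, also deposited by the authors, holds linear values with a median of 131.194 in the 6 HaCaT columns and HEK293T R348X, 131.198 in HEK293T control and 131.191 in the other 2. Its values rank the spots as the mean signal does (Spearman 1.0) and share one distribution, so they look like quantile-normalized mean signals without background subtraction. Which software made them is not given in the sources used here.

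Processed signals were set to log2 after dividing by the 75th percentile of each array. The main choices were made before the data were examined. A gene entered a comparison of 2 arrays when its spot was well above background on at least 1 of them, and was read from the probe with the highest mean signal over the 10 arrays. Only protein-coding genes were used: 27218 probes matched 18630 of them, 6252 genes having several probes. Probe positions are those of the array annotation (hg19), and gene names were updated with a RefSeq table of GRCh38.p14. Names were matched by transcript accession for 30004 probes, by symbol for 3112 and by older symbol for 487, and 16996 stayed unmatched. Per the raw files, the gene name differed at 22.55% of spots between the annotation releases of the 2 lines' files, and the newer one was read. Spots that the deposited files mark as non-uniform or as population outliers were left out, the spots of a probe were averaged, and no spot was saturated. The share of spots well above background was 69.9% for HaCaT control, 66.7% for wild type, 72.3% for R142C, 73.2% for R348X, 76.4% for scrambled shRNA and 69.6% for TGM1 shRNA. It was 60.5% for HEK293T control, 64.9% for wild type, 59.1% for R142C and 67.2% for R348X. Per the file headers, the median coefficient of variation of replicate spots ran from 4.92% to 9.45%, which limits what 1 array can resolve. Where only 1 array was above background, a difference is a bound.

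Pairwise comparisons used a size rule of 2-fold, since 1 array per group allows no test. Each of 40 gene lists, fixed before the files were opened, was given as a median difference and placed among 10000 random lists matched on mean expression in 20 bins, as a description. Across lines, limma 3.58.1 fitted treatment and cell line to 8 arrays with an intensity trend and 3 residual degrees of freedom, calling genes at an adjusted p under 0.05 among those well above background on at least 2 arrays. Lists were tested with camera, at a preset correlation of 0.01 and with an estimated correlation, and with fry. A test over all 24 matchings of the 4 treatments between the lines is exact. Tools were R 4.3.3, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-image 0.26.0 and matplotlib 3.10.9.

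Genes were named by rule. TGM1 is always named. In each of 7 pairwise comparisons the 10 largest differences each way are named among genes at least 2-fold different and well above background on both arrays. For both lines, up to 10 each way are named by the smaller of the 2 differences, then genes past the adjusted p, and in each list described the members that differ most.

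The dim area of each array was found, after seeing the data, by smoothing the share of spots above background over the surface with an SD of 12 rows and 7 columns and splitting it by Otsu's method. Spots nearer to that threshold than 25% of the gap between the means of the 2 sides were left out of like areas as edge. A named gene is said to have deviating neighbours when at least 2 of the 8 nearest spots above background on both arrays were 2-fold different the same way.

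The steps were tested on simulated data. The size rule found 100 of 100 changes of 1.5 on the log2 scale. The limma fit found 17 of 100 changes of 1 and 73 of 100 changes of 2, with 7 false calls among 16696 genes. Of random lists, 16 of 400 fell outside the central 95%. The area step placed 99.2% of spots rightly, and the matching test found 100 of 100 shared effects and gave its smallest p in 3 of 100 cases without one. The simulations of the size rule, the limma fit and the matching test held independent noise without dim areas or slide effects. Their rates therefore do not carry over to the real arrays.

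Alternatives fixed beforehand were quantile normalization, normexp with an offset of 50 and quantile normalization, the series matrix, spots above background on every array compared, no filter, the mean over probes, no intensity trend, slide as a block, leaving out each array, the TGM1 probe left out and Spearman correlation. Added after seeing the data were like areas, dim-area spots left out of the fit, the neighbour filter, pairs that share a slide and the share of control RNA. Levels of Y-linked genes are not printed.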

Results

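Gene expression was measured with single-colour Agilent arrays in 2 human cell lines at 48 h. HaCaT, a line of immortalised keratinocytes, gave 6 arrays: control, wild-type TGM1, the TGM1 changes R142C and R348X, a scrambled shRNA control and combined TGM1 shRNA. HEK293T, a line derived from embryonic kidney, gave 4 arrays: control, wild-type TGM1, R142C and R348X. Every group held 1 array, so a difference between 2 arrays has no error and no p-value, and their number limits the precision. A difference of at least 2-fold is a size rule here, and all differences are on the log2 scale. The share of spots well above background ran from 59.1% on the HEK293T R142C array to 76.4% on the HaCaT scrambled shRNA array.

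TGM1 encodes the transglutaminase that cross-links proteins and lipids of the cornified envelope in keratinocytes. It was read by 1 probe on chromosome 14, from 24718451 to 24718510 (hg19). In HaCaT cells its level was 4.09 on the control array, 3.99 on the wild-type array, 4.37 on the R142C array and 3.99 on the R348X array. It was 4.13 with the scrambled shRNA and 3.13 with the TGM1 shRNA. In HEK293T cells the level was -2.59 on the control array, -2.72 on the wild-type array, -3.35 on the R142C array and -3.04 on the R348X array, all above background. The probe therefore read no higher TGM1 level on either array labelled as wild-type TGM1 than on its control: the differences were -0.10 in HaCaT and -0.14 in HEK293T cells. The HEK293T readings were dim, with processed intensities from 32.7 to 61.7. The array annotation gives the probe position 2586 in the transcript. Whether the probe's target lies within the cloned part of the gene is not given in the sources used here. A probe in an untranslated region would not read a clone of the coding sequence. These levels therefore do not show whether the constructs were expressed.

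All arrays carried a dim area in which fewer spots stood above background, covering 31.4% to 47.8% of the spots. On the HaCaT wild-type and R348X arrays the dim area lay elsewhere than on the other HaCaT arrays, while on the HEK293T arrays it lay in largely the same place. A gene is said to lie in like areas of a pair when its spots lay inside the dim area on both arrays or outside it on both. Between the HaCaT R348X and wild-type arrays, 0.625% of spots in like areas and 17.5% of spots in unlike areas were at least 2-fold different. For that reason many medians below are also given over the members in like areas.

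**Figure D1:**
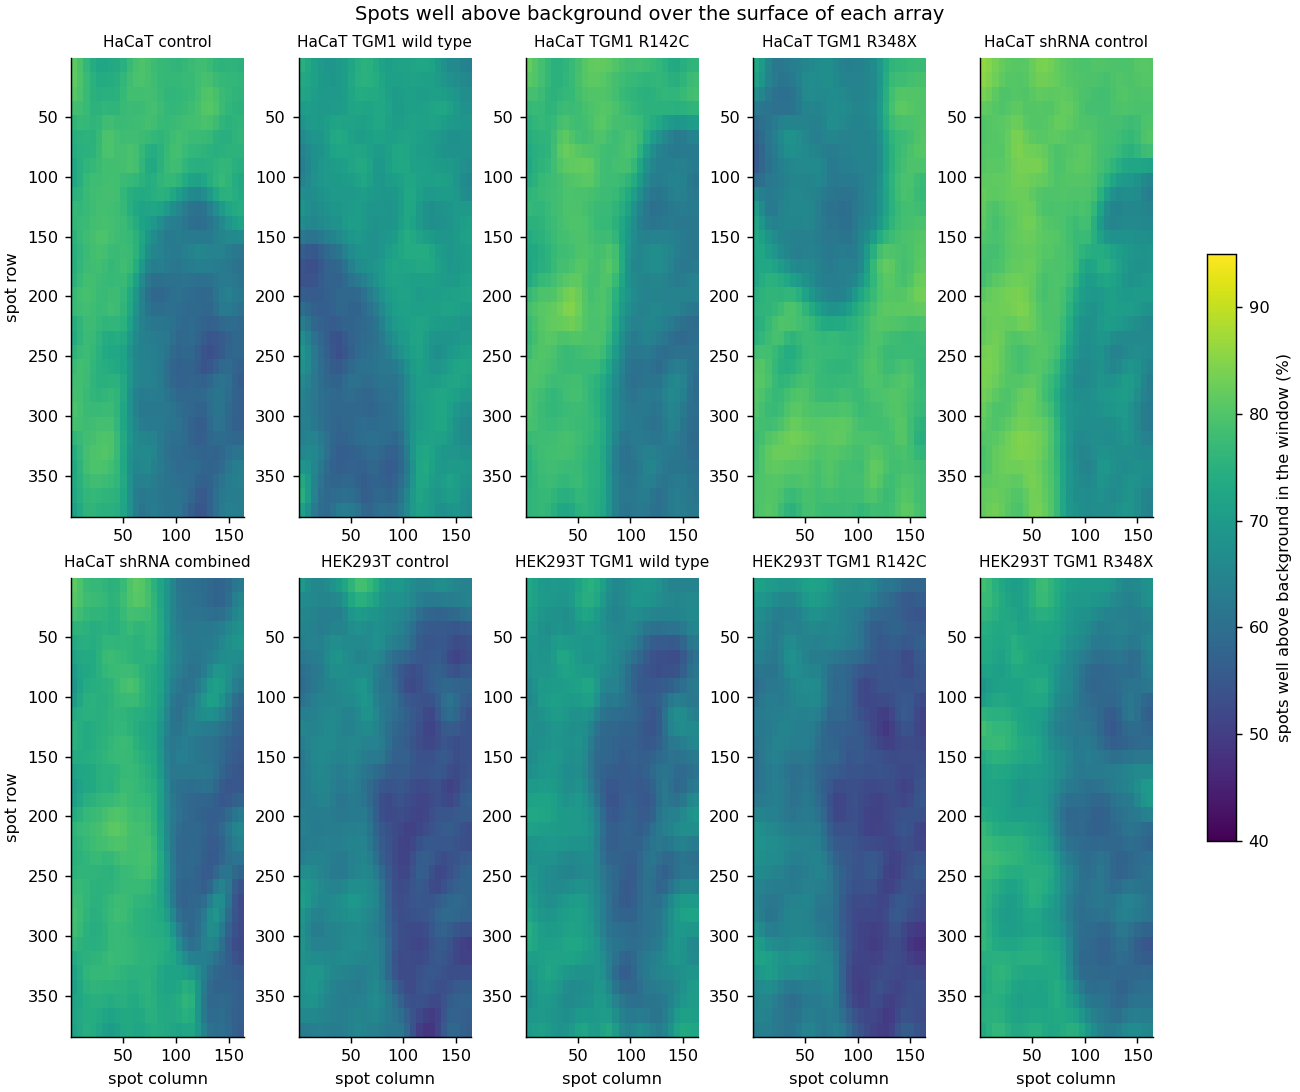
Percent of spots well above background in windows over the surface of each of the 10 arrays, by spot row and spot column, on a colour scale in percent. Darker windows mark the dim areas, which lay elsewhere on the HaCaT wild-type and R348X arrays than on the other HaCaT arrays and largely overlapped on the 4 HEK293T arrays.

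**Figure D2:**
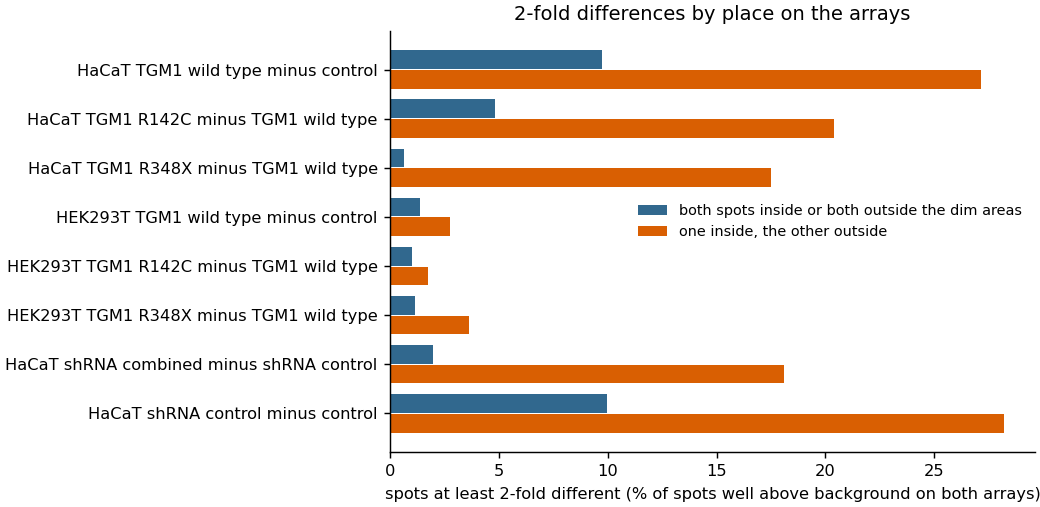
Percent of spots at least 2-fold different between 2 arrays, among spots well above background on both, for 8 pairs of arrays; bars part the spots in like areas from those with 1 array in its dim area and the other not. The share was higher in unlike areas for every pair, from 1.02% against 1.75% in HEK293T R142C minus wild type to 0.625% against 17.5% in HaCaT R348X minus wild type.

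The first comparison asked how HaCaT cells transfected with wild-type TGM1 differed from control cells. Interferon-stimulated genes, which encode antiviral effectors, were higher on the wild-type array: 38 of 41 measured members were at least 2-fold higher and 0 lower. The list median was 2.60, above all 10000 random lists matched on mean expression, and 2.47 over the 23 members in like areas. IFI44 was higher by 7.30, IFI6 by 5.51, OASL by 5.49 and HERC5 by at least 5.50. Targets of NF-kB and inflammatory cytokines were also higher, 16 of 32 by at least 2-fold, with a median of 1.06 (1.40 in like areas). IL6 was higher by 7.29, TNFAIP3, a feedback inhibitor of NF-kB, by 4.24 and IL1A by 4.19. Genes of the G1/S transition and DNA replication had a median of 1.23 (1.30 in like areas), with 20 of 30 at least 2-fold higher. Among these MCM10 was higher by 2.29, RRM2 by 2.21, the transcription factor E2F1 by 2.15 and CDC45, part of the replicative helicase, by 1.75.

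Immediate early genes, transcribed soon after a stimulus, had a median of 0.87 (0.83 in like areas), with 14 of 30 at least 2-fold higher and 2 lower. ATF3 was higher by 4.40, FOSL1 by 3.29 and JUN by 3.17. Epidermal serpins and antimicrobial peptides had a median of 0.88 (1.10 over 5 members in like areas), with S100A9 and SERPINB3 each higher by 2.48 and DEFB1 lower at -3.01. The amino acid response list had a median of 0.38 (0.75 in like areas) with members on both sides: GDF15 was higher by 2.20, DDIT4 lower at -2.14 and FGF21 lower at -2.24 or beyond. EGFR ligands and feedback genes had a median of 0.37 (0.32 in like areas), with AREG, an EGFR ligand, higher by 2.49 and SPRY4 lower at -2.31. The lists of p53 targets (-0.12), heat shock genes (0.16), the unfolded protein response (0.20) and G2/M genes (0.07) had medians inside the central 95% of random lists.

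In lists of keratinocyte differentiation the median difference of the genes between the wild-type and control arrays was below 0, with members on both sides. Of 32 suprabasal markers, 13 were at least 2-fold lower and 5 higher, with a median of -0.59 (-0.82 in like areas). The suprabasal keratins KRT77 and KRT1 differed by -3.16 and -3.04, the desmosomal cadherin DSC1 by -2.71, and S100A9 by 2.48. Of 34 cornified envelope precursors, 13 were at least 2-fold lower and 7 higher, with a median of -0.56 (-0.50 in like areas). Involucrin (IVL) differed by -3.62, RPTN by -3.27 and LCE2A by -3.00. The Notch pathway had a median of -0.72 (-0.57 in like areas), with the receptor NOTCH3 at -2.49 and MAML2 at -1.37, while the ligand DLL3 was higher by at least 2.65. The list labelled basal and stress keratins, which also holds KRT4 and KRT13, had a median of -0.49 (-0.28 in like areas). KRT4 stood at -3.83, KRT13 at -2.81 and KRT15 at -2.22. Desmosome and hemidesmosome genes had a median of -0.37 (-0.42 in like areas), with DSC3 at -1.47 and DSP, which encodes desmoplakin, at -1.08. The median of -0.46 over 22 keratinocyte markers became 0.01 over the 8 of them in like areas. Genes of ceramide and barrier lipid synthesis had a median of -0.33 (-0.21 in like areas), with DEGS2 at -1.89 and SPTLC3 at -1.56. Among the TGM family, the median was -0.47 over 8 members, with TGM6 at -2.51 or below and TGM7 higher by 1.88. The ichthyosis genes had a median of -0.11 over 29 members, with SULT2B1 at -2.31.

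By size, the genes named were IFI44, IL6, IFI6, OASL, CCL3 (5.38), MX1 (5.35), IFIT3 (5.14), GRB10 (5.02), CRYM (4.78) and NEURL3 (4.75) among those higher. Among those lower they were OLFM4 (-5.00), RAB26 (-4.53), MAL (-4.30), CLDN17 (-4.25), HS3ST6 (-4.12), PHGR1 (-4.10), DSG4 (-4.02), CYP3A5 (-3.99), KRT4 and CLDN8 (-3.68). Of these 20 genes, 11 lay in like areas, and 3 (IL6, OASL and CRYM) had at least 2 neighbouring spots that deviated the same way. In total 1762 of 16029 genes were at least 2-fold higher and 1563 lower (20.7%). In like areas the counts were 414 and 370 of 6826 genes (11.5%).

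The scrambled shRNA array, which carries no TGM1 construct, was set against the same control array as a background. There 38 of 41 interferon genes were at least 2-fold higher, with a median of 2.46 (2.54 in like areas), and IFI44 was higher by 7.45. The NF-kB list had a median of 0.93 (0.91 in like areas) and the G1/S list of 1.14 (1.10 in like areas), with 21 of 30 G1/S genes at least 2-fold higher. Suprabasal markers had a median of -0.64 (-0.39 in like areas), with KRT1 at -3.69, and cornified envelope precursors of -0.35 in both sets, with IVL at -3.82. In total 1437 of 16418 genes were at least 2-fold higher and 931 lower (14.4%). The R142C array had an interferon median of 2.24 against the control array, the R348X array 2.63 and the TGM1 shRNA array 2.43.

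The remaining pairs with the control array, R142C minus control and R348X minus control, are given as counts. For R142C 1371 of 16060 genes were at least 2-fold higher and 875 lower (14%). G1/S genes had a median of 0.83, suprabasal markers of -0.42 and the list labelled basal and stress keratins of -0.85, with KRT4 at -3.37. For R348X 2144 of 16541 genes were at least 2-fold higher and 1977 lower (24.9%), of which 307 and 263 of 4609 lay in like areas (12.4%). G1/S genes had a median of 1.20 there, suprabasal markers of -1.02 and cornified envelope precursors of -0.52.

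**Figure D3:**
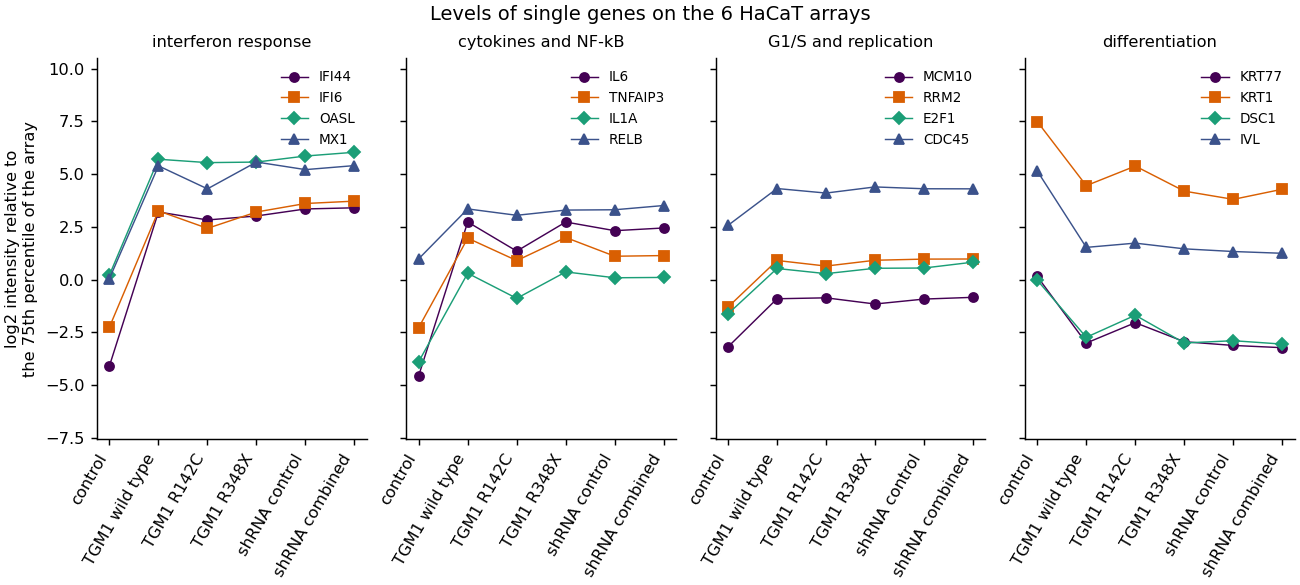
Level of single genes (log2 intensity relative to the 75th percentile of the array) on each of the 6 HaCaT arrays, 1 point per array, in 4 groups of genes. The control array stood apart from the other 5: MX1 was at 0.04 there and between 4.30 and 5.58 elsewhere, and IVL was at 5.15 there and between 1.25 and 1.73 elsewhere.

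The comparison of R142C with wild type asked what the amino acid change altered in HaCaT cells. Interferon genes were lower on the R142C array: 8 of 41 were at least 2-fold lower and 0 higher, with a median of -0.50 (-0.74 in like areas), below all random lists. The antiviral GTPase MX2 differed by -1.97, CMPK2 by -1.51, BST2 (tetherin) by -1.25 and OAS1 by -1.09. The NF-kB list had a median of -0.24 (-0.32 in like areas), with IL6 at -1.38, CCL5 at -1.35, CXCL8 at -1.23 and IL1A at -1.19. Proteasome subunits had a median of -0.49 (-0.50 in like areas), with PSMD3 at -0.70, PSMD14 at -0.68 and 0 of 31 past 2-fold. Ribosomal proteins had a median of -0.37 and the mitochondrial respiratory chain of -0.30 (turning to 0.02 after normexp), near the medians of random lists as bright (-0.36 and -0.33), so bright genes as a whole lay lower on the R142C array in this scaling. Replication-dependent histones had a median of -0.44 (-0.51 in like areas), with H3C10 at -0.70. Desmosome and hemidesmosome genes had a median of 0.26 (0.19 in like areas), with DSC3 higher by 1.03. Cornified envelope precursors had a median of 0.34, which was 0.05 in like areas, with LCE2A higher by 2.52. Suprabasal markers had a median of 0.26 (0.28 in like areas), with KRTDAP and DSC1 each higher by 1.05. The Notch list had a median of 0.23 (0.28 in like areas), with NOTCH3 higher by 1.26, and cholesterol synthesis of 0.17 (0.16 in like areas), with SC5D higher by 0.74.

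The scrambled shRNA array shared a slide with the R142C array, and most genes lay in like areas of that pair. There 6 of 41 interferon genes were at least 2-fold lower, with a median of -0.50 (-0.51 in like areas), MX2 at -1.80, CMPK2 at -1.43 and IFI6 at -1.18. The NF-kB list had a median of -0.25 (-0.21 in like areas) and the proteasome of -0.46 (-0.44 in like areas). Random lists matched to the interferon genes on mean expression had a median of -0.05. That mean covers both lines, and interferon genes were brighter on the HaCaT arrays, so these lists were not as bright there. Suprabasal markers had a median of 0.43 (0.42 in like areas), with 6 of 32 at least 2-fold higher, KRT1 by 1.58, S100A8 by 1.32 and SBSN by 1.31. Desmosome and hemidesmosome genes had a median of 0.43 (0.44 in like areas), with PLEC higher by 0.91. Cornified envelope precursors had a median of 0.37 (0.34 in like areas), with PI3 higher by 1.57 and SPRR1A by 1.19. Serpins and antimicrobial peptides had a median of 0.41, the same in like areas, with PI3 and S100A8 in the lead.

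Between R142C and wild type, the genes named by size were ADD3 (4.22), CRYGN (4.15), KRTAP13-4 (3.52), OR10G9 (3.52), ZNF568 (3.40), GPR142 (3.25), FSD2 (3.18), GPR15 (3.11), KRTAP23-1 (8.59-fold) and C3orf70 (3.09) among those higher. Among those lower they were SLC35G2 (-3.92), MYH7 (-3.80), FAM186A (-3.65), LYZL1 (-3.55), HEPH (-3.40), OR10J5 (-3.33), SHC3 (-3.23), GPR32 (-3.09), TRPC1 (-3.04) and TRIM67 (-3.03). Only ADD3 of these 20 lay in like areas, and 11 had at least 2 neighbouring spots that deviated the same way, ADD3 among them. Ranked over genes in like areas with fewer such neighbours, UGT2B10 (2.44), STMN4 (2.04) and ABLIM3 (1.87) led those higher and CPNE4 (-2.97), CLIC2 (-2.56) and MTCL1 (-2.46) those lower. That ranking was chosen after the values were seen. In total 1328 of 16137 genes were at least 2-fold higher and 855 lower (13.5%), and in like areas 179 and 40 of 5843 (3.75%).

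The comparison of R348X, which ends the protein early, with wild type asked the same of HaCaT cells. The gene groups set apart above differed little between these arrays. The interferon list had a median of 0.03 with 0 of 41 members past 2-fold (-0.14 in like areas), the NF-kB list of 0.03 (0.04 in like areas) and the G1/S list of 0.01 (0.00 in like areas). Suprabasal markers had a median of -0.12 (-0.09 in like areas), at percentile 0.15 of random lists, with DSG1, a desmosomal cadherin, at -1.07 and CDSN, which encodes corneodesmosin, at -0.92. Cornified envelope precursors had a median of -0.06 (-0.10 in like areas), with LCE2A higher by 2.85 and LCE2B at -2.70 or below. The ichthyosis genes had a median of 0.01 with the lipase LIPN higher by 2.10.

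The genes named by size for R348X minus wild type were GPR15 (3.35), GPR142 (3.23), CRYGN (3.17), OR10G9 (3.14), PDK4 (3.13), ACSM6 (3.12), OR3A3 (3.06), KRTAP13-4 (2.98), KRTAP23-1 (2.92) and CHIA (2.87) among those higher. Among those lower they were FAM186A (-4.21), MYH7 (-3.94), OR6P1 (-3.69), SLC35G2 (-3.58), TRPC1 (-3.48), NTMT2 (-3.28), SHC3 (-3.24), HYDIN (-3.23), TRIM67 (-3.19) and SOX3 (-3.18). Of these 20, 0 lay in like areas and 8 had deviating neighbours. In like areas UGT2B10 (2.45), STMN4 (1.99), CPNE4 (-2.96) and MTCL1 (-2.82) led by the ranking chosen later, as they did for R142C against the same wild-type array. In total 925 of 16313 genes were at least 2-fold higher and 1001 lower (11.8%), and in like areas 31 and 21 of 5284 (0.984%).

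The shRNA comparison asked what lowering TGM1 did in HaCaT cells. The TGM1 shRNA array lay alone on its slide and the scrambled shRNA array on another. Treatment and slide therefore cannot be told apart in this pair. TGM1 was lower with the TGM1 shRNA than with the scrambled shRNA, at -0.99, just short of 2-fold (1.99-fold). Its probe did not lie in like areas of the pair. Over 6 members of the TGM family the median was -0.47 (-0.42 in like areas). F13A1, the coagulation factor XIII A chain, stood at -2.74, and its level was as low on the R348X array (-4.96) as on the TGM1 shRNA array (-5.03). Interferon genes had a median of 0.11 (0.12 in like areas), above 99.79% of random lists, with CXCL10 higher by at least 1.09. Suprabasal markers had a median of 0.03 (0.01 in like areas), with CALML5 higher by 1.31 and KRT1 by 0.48, and cornified envelope precursors of -0.04 (0.02 in like areas), with 0 of 36 past 2-fold. The NF-kB list had a median of 0.04 and the ichthyosis genes of 0.08, with LIPN higher by 2.06. Replication-dependent histones had a median of 0.20 (0.19 in like areas), with H3C2 higher by 0.62, and the mitochondrial respiratory chain of 0.17 (0.10 in like areas), with COX7B higher by 0.65.

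The genes named by size for the shRNA pair were OR10C1 (5.88), TGFB2 (4.46), AVP (3.80), ASB11 (3.09), TAS2R50 (2.96), GLTPD2 (2.94), KYNU (2.72), SBK2 (2.61), DCST1 (2.59) and OR8B4 (2.58) among those higher. Those lower were VCAN (-3.28), MAP3K21 (-3.28), CFAP276 (-3.18), TRIM67 (-3.17), SOX8 (-3.01), MC3R (-2.99), NEURL1 (-2.98), GCSAM (-2.92), CCDC141 (-2.92) and OR51I2 (-2.89). Of these, ASB11, GLTPD2, OR8B4 and the kinase gene MAP3K21 lay in like areas, and 10 had deviating neighbours. MAP3K21 stood at 5.22 with the scrambled shRNA and at 1.94 with the TGM1 shRNA. In total 327 of 16450 genes were at least 2-fold higher and 652 lower (5.95%), which became 394 and 496 after quantile normalization. In like areas the counts were 66 and 240 of 11596 (2.64%).

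In HEK293T cells wild-type TGM1 against control asked the same question in cells that are not keratinocytes. The heat shock list had a median of 0.12 over 24 members (0.20 in like areas), above all random lists, with 2 at least 2-fold higher and 0 lower. The inducible HSP70 gene HSPA1A was higher by 2.57, HSPA6 by 1.11 and HSPA1B by 0.95, while HSPA1L was lower at -0.78. HSPA1A was well above background but dim on the control array, which limits the precision of its difference. Targets of p53 had a median of 0.28 (0.18 in like areas), also above all random lists, with the stress cytokine GDF15 higher by 1.67, the DNA repair gene DDB2 by 0.94, PHLDA3 by 0.91 and PLK2 by 0.89. RELB, a subunit of NF-kB, was higher by 2.01, while the NF-kB list as a whole had a median of -0.04 (-0.03 in like areas). Interferon genes had a median of -0.09 (-0.08 in like areas) with 0 of 30 past 2-fold, and G1/S genes of 0.06 in both sets, above 99.97% of random lists, with RRM2 at -0.46. Of the differentiation lists, suprabasal markers had a median of 0.07 (-0.02 in like areas), with GRHL3 higher by 1.53, and cornified envelope precursors of 0.02 (0.01 in like areas). Replication-dependent histones had a median of 0.14 (0.27 in like areas), with H4C8 higher by 0.59.

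The genes named by size were GNRH2 (2.90), CCDC43 (2.69), MDFI (2.67), ZNF823 (2.60), HSPA1A, PGBD5 (2.49), GPSM3 (2.32), ADAM12 (2.21), CDX1 (2.04) and RELB among those higher. On the lower side stood LYPD8 (-3.59), AMACR (-2.78), GCG (-2.72), FRMD1 (-2.56), KISS1 (-2.50), CDHR2 (-2.20), RUNDC3A (-2.12), MAB21L2 (-1.95), MEFV (-1.93) and MUC6 (-1.91). Of these 20, 9 lay in like areas and 7 had deviating neighbours. A second probe read no such difference for ADAM12 (0.05) and CDX1 (-0.02). In total 356 of 15257 genes were at least 2-fold higher and 221 lower (3.78%), and in like areas 157 and 97 of 10452 (2.43%). The larger side turned with the scaling: 245 higher and 293 lower after quantile normalization, 41 and 60 after normexp, and 42 and 60 in the series matrix.

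**Figure D4:**
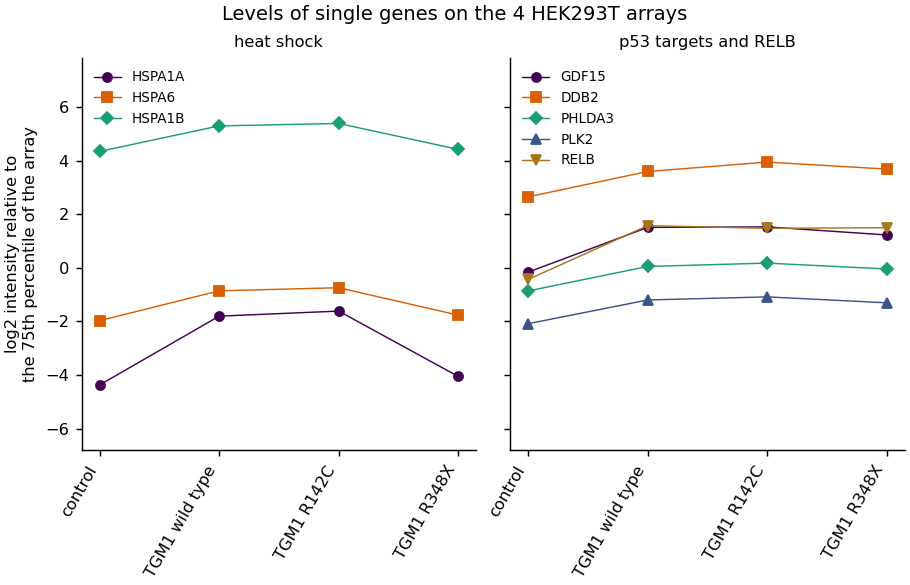
Level of single genes (log2 intensity relative to the 75th percentile of the array) on each of the 4 HEK293T arrays, 1 point per array. HSPA1A stood at -4.37 on the control array and -4.05 on the R348X array, against -1.80 on the wild-type and -1.61 on the R142C array, while RELB stood at -0.43 on the control array and between 1.47 and 1.57 on the other 3. The median spot inside the dim area stood at -3.82 on the control array and -3.65 on the R348X array. HSPA1A was thus dimmer than that median spot on both.

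Between the R142C and wild-type arrays of HEK293T cells the heat shock list had a median of -0.01 in both sets, with HSPB1 higher by 0.35 and HSPA1A by 0.19. The p53 list had a median of 0.10 in both sets, above 98.94% of random lists, with TP53I3 higher by 0.38 and DDB2 by 0.35. Against the control array, R142C had a heat shock median of 0.20, with HSPA1A higher by 2.75, and a p53 median of 0.42, with GDF15 higher by 1.69. Basal and stress keratins had a median of 0.19 (0.20 in like areas) between R142C and wild type, with KRT6B higher by at least 2.21 and KRT14 at -1.97 or below. The interferon list had a median of 0.05 (0.04 in like areas), with IFNL1 higher by 1.12, cornified envelope precursors of 0.03 (0.06 in like areas) and suprabasal markers of -0.04 in both sets, with CALML5 higher by 1.99.

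The genes named by size for this pair were RUNDC3A (2.71), AMACR (2.65), CRYAA (2.22), TMIGD3 (2.01), CALML5, FRMD1 (1.98), CDHR2 (1.94), LMOD2 (1.91), RASA2 (1.89) and RLBP1 (1.81) among those higher. Among those lower they were ANTXR2 (-4.39), EDRF1 (-4.16), STARD3NL (-3.58), PKD2 (-3.27), F12 (-3.26), TRAPPC10 (-2.90), CYB561A3 (-2.70), CBX1 (-2.60), BRPF1 (-2.59) and MRPL2 (-2.59). Other probes of 4 of these genes read no 2-fold difference: ANTXR2 (-0.31), EDRF1 (0.17), TRAPPC10 (-0.14) and CBX1 (0.03). RUNDC3A, AMACR, FRMD1 and CDHR2 were also named as lower on the same wild-type array against control. Their differences are therefore not particular to R142C. Of the 20, 12 lay in like areas and 3 had deviating neighbours. In total 220 of 15218 genes were at least 2-fold higher and 245 lower (3.06%), and in like areas 133 and 78 of 10173 (2.07%). Against the control array the counts were 261 and 182 of 14756 (3%), which became 41 and 64 after normexp and 47 and 69 in the series matrix.

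The R348X array of HEK293T cells is named by its label; its data file carries the same change with 2 digits exchanged, and which is right is not given in the sources used here. Against the wild-type array its heat shock list had a median of -0.19 in both sets, below all random lists, with 1 of 24 members at least 2-fold lower and 0 higher. HSPA1A differed by -2.25, HSPA6 by -0.91, HSPA1B by -0.88 and the small heat shock protein gene CRYAB by -0.58. HSPA1A was well above background but dim on the R348X array. Against the control array the heat shock median was -0.01, with HSPA1A higher by 0.32. Targets of p53 had a median of -0.05 against wild type (-0.03 in like areas) and of 0.25 against control, with GDF15 higher by 1.39 and DDB2 by 1.04 against control. The unfolded protein response had a median of 0.10 against wild type (0.12 in like areas), with VLDLR higher by 0.51 and DDIT4 by 0.39. Hypoxia and glycolysis genes had a median of 0.15 (0.11 in like areas), with ANKRD37 higher by at least 3.64 and SLC2A3, a glucose transporter, by 0.54. In the limma fit of both lines with dim-area spots left out, ANKRD37 stood at -3.80 for wild type minus control. It stood at 3.69 for R142C minus wild type there, so its difference was not particular to R348X. The vitamin D and retinoid list had a median of 0.18 in both sets, with PLAAT4 higher by just under 2-fold. The interferon list had a median of 0.02, cornified envelope precursors of 0.02 and suprabasal markers of -0.05, with CALML5 higher by 1.89.

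The genes named by size for R348X minus wild type in HEK293T cells were TAS2R13 (3.60), AMACR (2.76), RUNDC3A (2.67), GCG (2.56), FRMD1 (2.25), LMAN1 (2.15), MEFV (2.07), SPRN (2.02), CDHR2 (1.96) and ECHDC3 (1.89) among those higher. Among those lower they were MDFI (-2.66), ANKRD33 (-2.46), TRIO (-2.29), HSPA1A, C11orf21 (-2.19), RALYL (-2.00), TMEM247 (-1.99), ITPA (-1.99), PCOLCE2 (-1.93) and TRIM38 (-1.82). A second TRIO probe read 0.15. AMACR, RUNDC3A, GCG, FRMD1, MEFV and CDHR2 were also named as lower on the same wild-type array against control, and MDFI and HSPA1A as higher. Their differences are therefore not particular to R348X. Of the 20, 12 lay in like areas and 3 had deviating neighbours. In total 210 of 15713 genes were at least 2-fold higher and 345 lower (3.53%), which became 37 and 32 after normexp, and in like areas 108 and 132 of 10850 (2.21%). Against the control array 201 of 15486 genes were at least 2-fold higher and 152 lower (2.28%), and the larger side turned with the scaling: 159 and 165 after quantile normalization, 34 and 36 after normexp, and 36 and 40 in the series matrix.

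Genes that differed the same way in both lines were counted for each contrast. For wild type minus control, 91 of 14433 genes did so, against 40.9 expected if the lines were independent, while 60 differed in opposite ways, also against 40.9 expected. RELB (2.37 in HaCaT and 2.01 in HEK293T cells) and GDF15 (2.20 and 1.67) were among the 10 highest, with OR10J5 (3.61 and 2.51), TAS2R50 (3.91 and 2.06), UBASH3B (3.14 and 1.97), HBB (1.89 and 1.85), TPBGL (2.54 and 1.84), LCT (1.64 and 1.69), LRIT1 (1.63 and 1.86) and CCDC179 (1.79 and 1.62). The lowest were PGLYRP3 (-2.02 and -2.09), XKRX (-1.66 and -1.62), RELN (-2.02 and -1.53), TMEM253 (-1.71 and -1.49), MMAA (-1.42 and -1.47), CCDC178 (-1.74 and -1.30), KIAA1755 (-1.25 and -1.82), KRT4 (-3.83 and -1.24), PADI3 (-1.18 and -1.85) and BCAS1 (-2.29 and -1.16). In like areas of both lines the count was 9 against 5.95 expected. It was 5 after normexp, 6 in the series matrix, 20 above background on every array and 272 without a filter. Expected counts were not made for these settings.

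For R142C minus wild type the count in both lines was 70 against 20.9 expected, with 53 opposite against 20.5. In like areas it was 3 against 1.40. RASA2, a GTPase-activating protein, was the highest in both lines (1.78 in HaCaT and 1.89 in HEK293T cells) and lay in like areas of both. It was followed by FRMD1, OR1A2, CCDC178, REPS2, LY86, RIT2, DCT and RUNDC3A, which did not lie in like areas in either line. In like areas of both lines RASA2 was followed by OR1L8 (1.772 and 1.135) and OR2G2 (2.621 and 1.074). The lowest were OR10J5 (-3.33 and -2.48), TAS2R50 (-2.20 and -1.90), ZNF677 (-1.58 and -1.61), OR10G3, KRTAP4-3, SATB1 (-2.46 and -1.55), OR1F1, CCDC183 and LRIT1, though the mean over its probes put ZNF677 at 0.13 in HEK293T cells. For R348X minus wild type the count was 64 against 25.2 expected, with 56 opposite against 25.1, and 1 against 0.356 in like areas. Its highest genes were CD2 (2.43 and 2.85), SCART1, SPRN, CCDC178, OR1A2, RIT2, ELN, PGLYRP3, KISS1 and MEFV, though the mean over its probes put CD2 at -0.09 in HaCaT cells. Its lowest were TMIGD3 (-1.94 and -1.89), OR10A4, TULP1, THRSP, PCDHA13, MALRD1, ANKRD33, ELOVL3, GPR52 and SRD5A2. Both contrasts share the wild-type arrays with wild type minus control. There OR10J5, TAS2R50 and LRIT1 were among the highest and CCDC178 and PGLYRP3 among the lowest.

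Against the control arrays, 47 genes differed the same way in both lines for R142C against 23.9 expected, and 43 in opposite ways against 21.9. For R348X 102 differed the same way against 32.8 expected, and 44 in opposite ways against 32.6. In like areas of both lines R142C had 20 higher against 8.29 expected, 3 lower against 2.40 and 9 opposite against 9.21, and R348X had 3 the same way against 2.35. For R142C the highest were OR2G2 (2.13 and 2.44), KRT6B (2.40 and 2.11), RELB (2.06 and 1.91), GDF15 (1.99 and 1.69), RASA2 (1.67 and 2.29), GREM1, ATP6V1C2, OR51B5, SPRR2E and PROKR2. The lowest were CYP26A1 (-1.60 and -1.55), SLC9C2, SATB1, C20orf204, BCAS1, SULT2A1, BPIFC, XKRX, RELN and HES2. For R348X the highest were ROBO4 (1.95 and 2.01), RELB (2.31 and 1.93), RYR2, OR51B5, TAS2R40, TRHR, SH3GL3, LHFPL3, GNRH2 and ADAM12. The lowest were RELN (-2.86 and -2.32), CCDC27, SEC16B, SLC9C2, OR5D16, JAML, XKRX, BCAS1, KRT72 and TMIGD3.

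RELB was the single gene that passed the additive limma fit of treatment and cell line over 8 arrays. In the mean of the 3 TGM1 constructs minus control it rose by 2.10 ± 0.14 (SE; 3 residual degrees of freedom), with an adjusted p of 0.035. It was higher on 6 of 6 construct arrays than on the control array of its line. RELB lies on chromosome 19, from 45541385 to 45541444 for its probe (hg19). Its level in HaCaT cells was 0.98 on the control array, 3.35 with wild type, 3.05 with R142C and 3.30 with R348X, and 3.31 with the scrambled shRNA, which carries no TGM1 construct. RELB's probe did not lie in like areas of any construct pair with control in HaCaT cells, nor of the wild-type pair in HEK293T cells. It was clear of the dim areas on 2 of 8 arrays, so RELB could not be fitted with dim-area spots left out. GDF15 was higher by 1.84 ± 0.18 (SE) with an adjusted p of 0.208 over all genes in limma. Adjusted over the list alone its p was 0.000649 in limma, the list being the p53 targets. That p is not corrected for the other lists or for genes outside the list, so GDF15 is not called. GDF15 was clear of the dim areas on 3 of 8 arrays, the HaCaT control array not among them. GDF15 therefore could not be fitted with dim-area spots left out either. The RELB call was lost without any one array except the HEK293T control (adjusted p from 0.269 to 0.702), with slide as a block (0.513), after normexp (0.11), in the series matrix (0.0978) and without the intensity trend (0.465). The difference itself stayed near its size in these fits, from 1.95 ± 0.15 (SE) without the HaCaT control array to 2.13 ± 0.18 (SE) without the HEK293T wild-type array and 2.13 ± 0.17 (SE) without the HEK293T R348X array. For single contrasts limma called 0 of 16696 genes: wild type minus control had 696 genes at an unadjusted p under 0.05, R142C minus wild type 215, R348X minus wild type 115, R142C minus control 423 and R348X minus control 656.

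The gene lists were tested in the same fit with camera at a preset correlation of 0.01. For wild type minus control the interferon list rose, with a median of 1.37 (limma camera, adjusted p = 5.89e-15), as did G1/S genes (0.58, adjusted p = 2.14e-10), the NF-kB list (0.57, adjusted p = 8.57e-05), immediate early genes (0.44, adjusted p = 0.000493) and heat shock genes (0.28, adjusted p = 0.00254). The mitochondrial respiratory chain fell, with a median of -0.14 (adjusted p = 0.0229). All these calls were lost in camera with an adjusted p = 0.705 with an estimated correlation, and in fry (adjusted p 0.638 or above). For R142C minus wild type the proteasome (median -0.22) and ribosomal proteins (median -0.20) fell, each with an adjusted p = 2.51e-05 at the preset correlation and an adjusted p = 0.863 with an estimated correlation. Against 2 list calls here, this contrast had 1 after quantile normalization and 7 with slide as a block. Bright genes as a whole lay lower on the HaCaT R142C array. For R348X minus wild type heat shock genes fell, with a median of -0.12 and a camera adjusted p = 0.042, against an adjusted p = 0.997 with an estimated correlation. For R348X minus wild type the list calls numbered 1 here, 0 after normexp, 0 in the series matrix and 8 with slide as a block. At the preset correlation 11 lists were called for R142C minus control and 4 for R348X minus control, and 0 for either with an estimated correlation or in fry. For wild type minus control the interferon median joins 2.60 in HaCaT cells and -0.09 in HEK293T cells, G1/S 1.23 and 0.06, NF-kB 1.06 and -0.04, and immediate early genes 0.87 and -0.03, so these rises rest on the HaCaT arrays. For R142C minus wild type the proteasome joins -0.49 and 0.04, and ribosomal proteins -0.37 and -0.01, which rest on the HaCaT arrays too.

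Whether the treatments had like effects in both lines over all genes was tested by matching the 4 treatments of one line to those of the other. The mean correlation of matched treatments across 16696 genes, which are not independent replicates, was 0.0044. Of the 24 possible matchings 11 gave a value as high, an exact one-sided permutation p of 0.458, and the smallest p this design allows is 0.0417.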

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

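The tests of explanations in this part were chosen only after the results were seen, while limma, camera and quantile normalization had been planned. Some results differed between the 2 lines, and these line differences were not tested. The genes at least 2-fold different in opposite directions numbered 60 for wild type minus control, 53 for R142C minus wild type, 56 for R348X minus wild type, 43 for R142C minus control and 44 for R348X minus control. Some lists also had opposite signs in HaCaT and HEK293T cells. For wild type minus control these were ribosomal proteins (-0.151 and 0.012, a sign that turned with the scaling in both lines) and keratinocyte markers (-0.455 and 0.161, the first turning in like areas). Keratinocyte markers also differed for R142C minus wild type (0.158 and -0.069, the first turning in like areas and the second with a filter on every array), the unfolded protein response for R348X minus wild type (-0.063 and 0.096) and desmosome genes for R348X minus control (-0.364 and 0.059, the second turning in the series matrix).

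The first pattern weighed is the 2-fold differences between the HaCaT R348X and wild-type arrays, led by genes such as GPR15, FAM186A and MYH7. Uneven hybridisation predicts that they gather where only 1 array is dim, and the share of 2-fold spots was 27.9 times as high there as in like areas. Lying on different slides did not bring more 2-fold genes in like areas: 0.984% were 2-fold different across slides, against 4.16% within a slide for R348X minus R142C. That is another pair of treatments, and the pattern lies mostly in unlike areas. A slide effect there is therefore not excluded. An effect of R348X itself may remain in the 52 of 5284 genes in like areas: within HaCaT cells it could not be tested with 1 array, and across both lines the limma fit called 0 genes.

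The second pattern is the interferon genes, led by IFI44 and IFI6, that were higher on 5 HaCaT arrays than on the control array. Dim areas are excluded as the cause, because the list median in like areas was 2.465. The TGM1 construct is excluded as the sole cause, because the scrambled shRNA array, which carries none, had a median of 2.463. A control culture that stood apart and a delivery of nucleic acid that it did not share cannot be told apart: each of the 5 medians was at least 2.237, there was no second HaCaT control array, and whether the control cells received nucleic acid is not given in the sources used here.

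The third pattern is the HaCaT R142C array, which stood part of the way back towards the control array in interferon genes such as MX2. RNA of the control culture mixed in is excluded as the sole cause: genes lower on the control array would need 39.9% of control RNA and genes higher on it 5.70%. A small share of control RNA beside another cause is not excluded. Bright lists such as ribosomal proteins (-0.37 against wild type) also lay lower on it. After quantile normalization, which gives all arrays the same distribution, the interferon median against the scrambled shRNA array was still -0.377. That argues against compression of the signal as the whole cause for the interferon genes, but does not exclude it. It lay below all random lists matched on mean expression, yet that mean covers both lines, and interferon genes were brighter on the HaCaT arrays. A lower uptake of the construct and an effect of R142C itself may each be the cause, and neither could be tested within HaCaT cells with 1 array; across both lines limma called 0 genes for R142C minus wild type, and camera gave the interferon list an adjusted p of 0.25.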

How the results depend on the processing

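Alternatives named like areas and dim-area spots left out were chosen after seeing the data. Unless a cause is given beside a value, the cause was not tested. No paired analysis was possible because each group has a single replicate, so replicate numbers pair nothing. Cell line entered the limma fit, and slide was tried as a block. That block set the HaCaT R142C and R348X arrays apart from the rest, so in HaCaT cells it cannot be told apart from these constructs. Signal over background limits the dim genes: without a filter more noisy genes were counted, and with one on every array fewer. Single genes kept direction and side in 661 of 912 cases after normexp, 677 of 911 in the series matrix, 884 of 914 after quantile normalization, 830 of 908 with the mean over probes and 906 of 914 without a filter. Above background on every array it was 723 of 723, which was fixed in advance, since that filter drops genes and leaves the other values unchanged. Without a filter, genes above background on both arrays also keep their values. List medians kept direction and side in 111 of 129 cases after normexp, 112 in the series matrix and 115 after quantile normalization. They did so in 122 above background on every array, 116 with the mean over probes, and 103 of 128 in like areas.

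Counts of 2-fold genes are given as normexp and series matrix. In HaCaT cells they were 1777 and 1965 for wild type minus control (3325 in the main setting), 864 and 1004 for R142C minus wild type (2183), 665 and 776 for R348X minus wild type (1926), 229 and 271 for the shRNA pair (979), 1092 and 1205 for R142C minus control (2246), 2069 and 2287 for R348X minus control (4121) and 1217 and 1308 for scrambled shRNA minus control (2368). In HEK293T cells they were 101 and 102 for wild type minus control (577), 89 and 92 for R142C minus wild type (465), 69 and 82 for R348X minus wild type (555), 105 and 116 for R142C minus control (443) and 70 and 76 for R348X minus control (353).

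Above background on every array compared, which tests fewer genes, the counts were 1235 for HaCaT R142C minus wild type, 1087 for R348X minus wild type and 525 for the shRNA pair, and in HEK293T cells 198, 146 and 174 for wild type minus control, R142C and R348X minus wild type, 180 for R142C minus control and 128 for R348X minus control. Without a filter, which tests more, they were 1514 for the shRNA pair and, in the same HEK293T order, 1450, 1272, 1398, 1094 and 1053. In like areas, which hold fewer genes, they were 784, 219 and 52 for HaCaT wild type minus control, R142C and R348X minus wild type, 306 for the shRNA pair, 1397 and 570 for HaCaT R142C and R348X minus control, 254, 211 and 240 for the 3 HEK293T pairs and 235 for HEK293T R348X minus control.

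Genes alike in both lines numbered, for normexp, series matrix, every array, no filter and like areas: 5, 6, 20, 272 and 9 for wild type minus control (91), 7, 9, 20, 219 and 3 for R142C minus wild type (70), 14, 15, 31, 173 and 1 for R348X minus wild type (64), 6, 7, 17, 157 and 23 for R142C minus control (47), and 6, 6, 29, 272 and 3 for R348X minus control (102).

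Calls of the limma fit depended on single arrays, and a lone sample left in an arm is assumed to vary like the other groups. All 5 single contrasts had 0 calls and the mean of the 3 constructs 1. Leaving out 1 array gave 0 to 470 calls for wild type minus control, 0 to 1 for R142C minus wild type, 0 to 1 for R348X minus wild type, 0 to 211 for R142C minus control, 0 to 481 for R348X minus control and 0 to 823 for the mean of the 3 constructs. The 470, 211, 481 and 823 calls came without the HEK293T control array, when the control level rests on the HaCaT control array alone. The RELB call (adjusted p 0.035 in the limma fit of 8 arrays) was lost without any one array other than the HEK293T control. In the fits where it was lost, the RELB difference stayed between 1.95 and 2.13, against 2.10. The mean of constructs gave 0 calls after normexp, in the series matrix, without trend, with slide as a block and with dim-area spots left out, where RELB could not be fitted. BTBD10, chosen after its values were seen, made the 1 call without HaCaT wild type (limma adjusted p 0.0169, 0.0196 and 0.0169), and ANKRD37, also so chosen, the 1 call with dim-area spots left out (limma adjusted p 0.0140, 0.00828 and 0.00667), in wild type minus control, R142C minus wild type and R348X minus wild type.

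List calls of camera at the preset correlation numbered 10 after normexp for wild type minus control (6), 1 after quantile normalization and 7 with slide as a block for R142C minus wild type (2), 0 after normexp, 0 in the series matrix and 8 with the block for R348X minus wild type (1), 7 with the block for R142C minus control (11), and 9 after normexp and 9 in the series matrix for R348X minus control (4). With an estimated correlation every setting gave 0 calls. In fry the 1 call was the list of ceramide and barrier lipid synthesis, named after its values were seen, above background on every array (limma fry, adjusted p 0.0388 for wild type minus control and 0.0276 for the mean of constructs). The exact permutation p of the matching test ran from 0.375 to 0.833. TGM1 passed 2-fold in the shRNA pair after quantile normalization (-1.003), normexp (-1.095) and in the series matrix (-1.142), against -0.995.

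Some values turned sign. Keratinocyte markers became 0.011 in like areas for HaCaT wild type minus control, -0.095 in like areas for R142C minus wild type, and 0.02 above background on every array for HEK293T R142C minus wild type. Ribosomal proteins became 0.028 after quantile normalization for HaCaT wild type minus control. For HEK293T wild type minus control they became -0.089 after quantile normalization, -0.105 after normexp, -0.102 in the series matrix, -0.023 with the mean over probes and -0.002 in like areas. Desmosome genes became -0.014 in the series matrix for HEK293T R348X minus control. With the mean over probes DNAH17 became -0.54 and CD2 -0.089 for HaCaT R348X minus wild type, and ZNF677 0.129 for HEK293T R142C minus wild type.

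Higher and lower genes shifted with the setting. HEK293T wild type minus control had 356 and 221, and 245 and 293 after quantile normalization, 41 and 60 after normexp, 42 and 60 in the series matrix and 86 and 112 above background on every array. HEK293T R142C minus wild type had 220 and 245, and 260 and 225 after quantile normalization and 97 and 49 above background on every array. HEK293T R348X minus wild type had 210 and 345, and 37 and 32 after normexp and 96 and 78 above background on every array. HEK293T R142C minus control had 261 and 182, and 200 and 203 after quantile normalization, 41 and 64 after normexp and 47 and 69 in the series matrix. HEK293T R348X minus control had 201 and 152, and 159 and 165 after quantile normalization, 34 and 36 after normexp and 36 and 40 in the series matrix. HaCaT R348X minus wild type had 925 and 1001, and 395 and 381 in the series matrix and 1349 and 1297 without a filter. HaCaT R348X minus control had 2144 and 1977, and 2005 and 2014 after quantile normalization. The shRNA pair had 327 and 652, and 394 and 496 after quantile normalization.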

Other observations

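Regulators of apoptosis split within HaCaT cells. Between the wild-type and control arrays PMAIP1, which encodes the death-promoting protein NOXA, was higher by 3.64 and BMF lower at -3.54, with FAS higher by 1.75 and a list median of 0.07. The scrambled shRNA array differed from the control array in the same genes, PMAIP1 by 3.57, BMF by -3.39 and FAS by 1.82. Among matrix metalloproteinases and inhibitors the median was 0.02, with PLAUR, the urokinase receptor, higher by 2.94, MMP13 at -2.42 and MMP10 at -1.66.

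Genes of vitamin D and retinoid metabolism also split, with a median of -0.22 between the wild-type and control arrays. DHRS9, a retinol dehydrogenase, was higher by 4.49, LRAT by at least 2.75 and CRABP2, which carries retinoic acid to the nucleus, lower at -2.67. Cholesterol synthesis had a median of -0.12, with SC5D at -1.63, TM7SF2 at -1.29 and INSIG1 at -1.29.

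Markers of the cell types were read on every array. Keratinocyte markers had median levels from 5.53 to 5.96 on the HaCaT arrays and from -4.67 to -3.04 on the HEK293T arrays. Markers of HEK293T cells had median levels from 0.58 to 0.75 on the HEK293T arrays and from -2.91 to -1.71 on the HaCaT arrays. Interferon genes had a median level of -0.19 on the HaCaT control array and from 1.76 to 2.45 on the other HaCaT arrays, and from -3.42 to -3.10 on the HEK293T arrays.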
